A study of Homo sapiens with 10 samples.

How the data were processed

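RNA of the human breast epithelial line MCF10A was measured on Affymetrix gene expression arrays, with 5 arrays of parental cells and 5 of cells in which the gene of histone H2A.X was knocked out. Per the labels' protocols, cells of both groups were grown in the same medium with serum, EGF, insulin, hydrocortisone and cholera toxin, cultured for 48 h and harvested, and labelled RNA was prepared from 1 ug of total RNA. The labels number the samples of each group from 1 to 5. They do not say whether these came from separate cultures, from a single knockout clone or from several.

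The deposited values are log2 signals per probe set, 1 column per array, already summarised and normalised by the authors. Per the submitters' processing notes, Affymetrix Expression Console and Partek 6.6 were used. The order of these tools, the summarisation method and any filter are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 1.13 to 13.87 with array medians of 4.26 to 4.35. An array median that close to the others leaves no shift between groups in overall signal, so a change of all transcripts together could not be seen in these values. For arrays, their number limits the precision: with 5 against 5, the median standard error of a log2 difference was 0.08.

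The table held 53617 probe sets. A gene was named only through the platform annotation supplied with the table, with symbols updated by Entrez identifier in the RefSeq gene table of GRCh38.p14. There were 16098 probe sets with 1 gene symbol, all of them matched by identifier, 0 with several symbols, and 37519 with no gene named here. The probe set with the highest mean over the 10 arrays stood for each of 14884 genes. Among the 779 genes with several probe sets, 5 had probe sets past the test in opposite directions. H2AX itself, CDH1, CDH2 and the 38 members of a histone list were not analysed here. The knocked out gene could therefore not serve as a check of the labels.

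Differences are knockout minus parental, tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the log2 values, with no covariate, no further normalisation and no filter on dim probe sets. Benjamini-Hochberg adjustment ran over all 14884 genes, and a gene passed the test at an adjusted p under 0.05. A count with an absolute log2 difference of at least 1, a 2-fold change, was also made. Of 33 gene lists written from general knowledge before the data were examined, 32 had at least 3 measured members, and 582 of the 974 places in the lists were filled by a measured gene. Each list was tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. The test was repeated with the correlation estimated from the data and with fry, which asks whether a list moves on balance in a single direction and makes no comparison with other genes. All p-values were two-sided.

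The genes named were taken by a rule that was fixed with the lists. It took TWIST1, SNAI2 and the other transcription factors of epithelial-mesenchymal transition (EMT). It took the 10 largest rises and the 10 largest falls among genes that passed the test, whose knockout arrays lay entirely on the same side of the parental arrays, and whose higher group mean exceeded the median of all gene means. It took up to 4 members of each list that passed with the same separation, ranked by absolute difference. It took VIM, FN1, EPCAM and MKI67 whatever their values, and would have taken H2AX, CDH1 and CDH2. Further members of the lists are named where a list is described and were chosen after their values were seen.

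Gene order along the chromosomes was taken from the same RefSeq table, for names and neighbours only. A running median over 21 consecutive genes was computed among the 7439 genes above the median signal. Runs of at least 40 genes whose running median stayed beyond 0.15 in the same direction were called stretches, and 1000 shuffles of the gene order showed what chance gave. The search for stretches, its limits and an alternative without the genes of the 3 stretches were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for this step, the exact permutation tests and the plots.

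The procedure was tested on simulated data with the real means and spreads of the 14884 genes and 200 genes changed by known amounts. It recovered 79% of the genes changed by 0.5 on the log2 scale and 97% of those changed by 1, and called 14 unchanged genes. A list of 25 genes shifted by 0.3 was found, and 0 of 30 unshifted lists were called. The simulated genes varied independently of each other, so false calls of lists whose genes are correlated were not examined. Only 200 genes were changed there, against 5108 called in the real data. Camera compares a list with the other genes, so the simulation does not show how lists fare against so many changed genes. The alternatives tried were quantile normalisation, centring of each array on its median, the mean of all probe sets of a gene, a filter on the 30% of genes with the lowest mean, an intensity trend in the variance, array weights, the replicate number as a block, leaving out each array in turn, all probe sets without choosing among those of a gene, an adjusted p under 0.01, and limma's treat against a 2-fold change. An alternative based on suffixes of probe set names was not run, because the names here carry none.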

Results

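The data were 10 arrays of MCF10A, an immortalised, non-tumorigenic line of human breast epithelium with basal features, 5 from parental cells and 5 from cells knocked out for the histone variant H2A.X, which is phosphorylated around DNA double-strand breaks. The array medians lay between 4.26 and 4.35 on the log2 scale in all 10 samples. Correlations across the 14884 genes, with 1 probe set each, were 0.991 to 0.996 within groups and 0.975 to 0.979 between them. The first principal component held 65.8% of the variance and separated the groups. The second held 7.53%, and on it knockout replicate 1 stood apart from the other knockout arrays, at 20.2 against -9.47 to -2.52. The question, as the series title puts it, was how loss of H2A.X relates to EMT and to its transcription factors TWIST1 and Slug, the product of SNAI2.

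Knockout cells had lost most of the signal of several epithelial genes and gained that of basal keratins. OCLN, which encodes the tight junction protein occludin, fell from 8.26 ± 0.10 to 3.53 ± 0.34 (log2, SD, n = 5 each), 26.6-fold lower in signal, a fold that is uncertain because the knockout mean lay under the median of every array. ESRP1, an epithelial splicing regulator, fell by 3.79 and the adhesion molecule gene EPCAM fell from 8.49 ± 0.05 to 6.35 ± 0.25. The basal keratin genes KRT15 and KRT14 rose by 3.24 and 2.59, and EHF, an epithelial transcription factor of the ETS family, rose by 3.05. SNAI2 rose from 10.86 ± 0.11 to 11.34 ± 0.08, while TWIST1 was at 5.44 ± 0.09 and 5.69 ± 0.33 and did not pass the test.

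Across the transcriptome, limma called 5108 of 14884 genes (34.3%), of which 2273 rose and 2835 fell. Of these, 418 differed at least 2-fold, 195 upward and 223 downward, and in 417 of the 418 all 5 knockout arrays lay on the same side of all 5 parental arrays. That separation was seen in 28.2% of all genes, against 0.794% by chance. The median difference over all genes was 0.00 on the log2 scale, on values already normalised by the authors. The p-values measure only the spread between these samples, which may be technical, because the labels do not say whether they were separate cultures or clones. The targeted gene was not analysed here, and the groups rest on the labels.

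The epithelial junction and identity genes moved in both directions. Of 34 measured members, 13 fell, 8 rose and 13 did not pass, with the same counts when adjusted over the list alone. Besides OCLN (probe set 16985704, adjusted p = 1.07e-10), ESRP1 (17070949, adjusted p = 1.84e-10) and EPCAM (16879863, adjusted p = 6.97e-09), the falls included the claudin gene CLDN7 (-1.64), the membrane protease gene ST14 (-1.36) and the junction scaffold gene TJP1 (-1.12). The rises included GRHL3 (0.82), the desmosomal plaque genes DSP (0.53) and JUP (0.53), and PPL (0.46), apart from EHF. The median was -0.10, and the list did not pass camera (adjusted p = 0.124, and adjusted p = 0.442 with an estimated correlation). Without the genes of 3 chromosomal stretches described below, which hold 5 of the members, the median was -0.14 and the adjusted p was 0.0279. OCLNP1, a pseudogene of OCLN whose probe set may share sequence with it, fell by 2.75. In the same knockout arrays 5 of 10 fibroblast markers rose and 2 fell (camera, adjusted p = 0.0157, and adjusted p = 0.171 with an estimated correlation).

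The basal epithelial and hemidesmosome genes rose as a list. Of 13 measured members, 9 rose, 2 fell and 2 did not pass, the same when adjusted over the list alone, with a median of 0.39 (camera, adjusted p = 0.000253, and adjusted p = 0.0835 with an estimated correlation). KRT16 rose by 1.44, KRT5 by 0.78 and EGFR, the receptor for the EGF in the medium, by 0.69, while the desmosomal cadherin genes DSC2 and DSG2 fell by 0.93 and by 0.21. KRT14, KRT15 and KRT16 lie in a stretch of chromosome 17 whose genes were higher in general. Without the 4 members in such stretches the median of the other 9 was 0.25 (camera, unadjusted p = 0.0216, and unadjusted p = 0.0718 with an estimated correlation). Among 24 luminal mammary genes 1 rose and 4 fell, or 1 and 3 adjusted over the list alone. XBP1 (-1.87), KRT18 (-0.94), GATA3 (-0.44) and FOXA1 (-0.29) fell and CD24 (1.94) rose. Their median was 0.01, while their mean was -0.06, in the direction of the test (adjusted p = 0.734), and the median was -0.06 without knockout replicate 1.

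**Figure D1:**
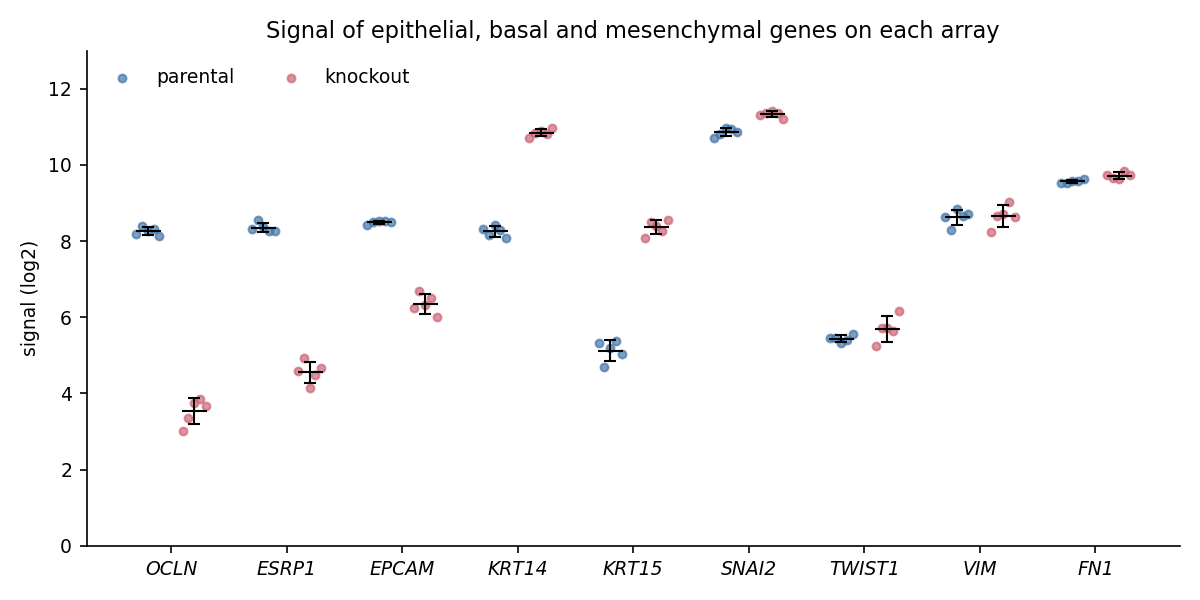
Signal (log2) of 9 genes on each of the 10 arrays, parental in blue and knockout in red, with horizontal bars at the group means and vertical bars of 1 SD (n = 5 each). OCLN, ESRP1 and EPCAM lay lower and KRT14, KRT15 and SNAI2 higher on every knockout array, while the arrays of TWIST1, VIM and FN1 overlapped.

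The EMT transcription factors showed small shifts. Of 13 measured members, FOXQ1 (0.98 ± 0.09, SE), TCF4 (0.54 ± 0.07), SNAI2 (0.48 ± 0.07) and ZEB2 (0.24 ± 0.06) rose, TWIST2 (-0.37 ± 0.07) fell, and 8 did not pass, with the same 4 and 1 when adjusted over the list alone. The SNAI2 difference (probe set 17077004) had an adjusted p of 6.88e-05 and every knockout array lay above every parental array. The TWIST1 difference (probe set 17055614) was 0.25 ± 0.13 (adjusted p = 0.168). Differences of the others were SNAI1 0.00, ZEB1 -0.04, PRRX1 0.05, GSC 0.11, SNAI3 0.12, TCF3 0.13 and KLF8 0.14. The signals of SNAI1, PRRX1, ZEB1 and GSC lay under the median of all gene means (5.49) in both groups, as did ZEB2, which passed. Those of SNAI3 and TWIST1 did so in parental cells. Differences of dim genes are compressed, so these small values do not show that the factors were unchanged. SNAI1 took the opposite sign under quantile normalisation and under centring. With an array left out ZEB1 ran from -0.09 to -0.01, PRRX1 from 0.01 to 0.10, GSC from 0.06 to 0.16, SNAI3 from 0.06 to 0.17 and KLF8 from 0.06 to 0.19. The median of the list was 0.13 (camera, adjusted p = 0.0462, and adjusted p = 0.115 with an estimated correlation). Without FOXQ1, in a test added after the result was seen, the median was 0.13 (camera, unadjusted p = 0.0642, and unadjusted p = 0.0870 with an estimated correlation). Leaving out parental replicate 1, 3 or 5, or knockout replicate 4 or 5, ended the call of the list, at adjusted p of 0.0611, 0.0509, 0.0531, 0.0544 and 0.0659. Without knockout replicate 1, TWIST1 passed the test (0.37, adjusted p = 0.0144), and without knockout replicate 5 its difference was 0.14.

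Mesenchymal genes did not move together. Of 18 measured members, 7 rose, 6 fell and 5 did not pass, or 8 and 6 adjusted over the list alone, with a median of 0.07 (adjusted p = 0.526), or 0.02 to 0.11 with an array left out. DCN, which encodes the matrix proteoglycan decorin, rose by 2.06 and the collagen crosslinking enzyme gene LOX by 1.01, S100A4 by 0.67 and CD44 by 0.50. The matrix genes TNC and FBN1 fell by 2.44 and by 1.03, and the receptor gene AXL fell by 0.49. VIM, which encodes vimentin, was at 8.63 ± 0.20 and 8.65 ± 0.29, and FN1, which encodes fibronectin, at 9.57 ± 0.05 and 9.72 ± 0.09 (n = 5 each). The VIM difference was 0.03 (adjusted p = 0.906) and that of FN1 was 0.15 (adjusted p = 0.0583). FN1 passed without knockout replicate 3 (0.18, adjusted p = 0.0398), under quantile normalisation (0.20, adjusted p = 0.0190), without the dimmest genes (adjusted p = 0.0341) and with an intensity trend (adjusted p = 0.00957).

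Among markers of other cell types, several fibroblast markers rose. Of 10 measured members, DCN, MFAP5 (1.49), FBLN1 (1.35), CCDC80 (1.20) and PDPN (0.56) rose, APOD (-0.40) and DPT (-0.38) fell, and 3 did not pass, the same adjusted over the list alone. Their median was 0.33 (camera, adjusted p = 0.0157, and adjusted p = 0.171 with an estimated correlation), and 0.88 without the dimmest genes. Of 10 endothelial markers only KDR, the receptor gene for VEGF, passed, with a rise of 1.69 (adjusted p of the list 0.272). Of 7 immune cell markers CSF1R (0.72) rose and CD14 (-0.76) and CD68 (-0.37) fell (adjusted p of the list 0.868), with a median of 0.01, or -0.07 without knockout replicate 1, and a mean of -0.05. Of 6 adipocyte markers PPARG (-0.61) fell (adjusted p of the list 0.513). Counts adjusted over the list alone were the same for these 3 lists.

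Stress response genes showed the lowest list medians. Of 19 measured amino acid stress response genes, which include targets of the transcription factor ATF4, 18 fell and 1, ATF5 (0.21), rose, also when adjusted over the list alone. The median was -1.50 (camera, adjusted p = 2.90e-17, and adjusted p = 0.0158 with an estimated correlation). DDIT3, which encodes the transcription factor CHOP, fell from 7.10 ± 0.25 to 4.46 ± 0.16 (n = 5 each), WARS1, which encodes the tryptophanyl-tRNA synthetase, fell by 2.48 (by its other probe set, -1.08), TRIB3 fell by 2.35, STC2 fell by 2.07, the asparagine synthetase gene ASNS fell by 1.94 and ATF4 itself fell by 0.60. All 10 measured unfolded protein response genes fell, also when adjusted over the list alone, with a median of -0.89 (adjusted p = 1.98e-10, and adjusted p = 0.0125 with an estimated correlation). They included HYOU1 (-2.65, and -1.25 by its other probe set), a chaperone gene of the endoplasmic reticulum next to the H2AX locus, XBP1 (-1.87), ERN1 (-1.47) and SEL1L (-1.28). HYOU1 and ERN1 lie in the stretches described below.

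Genes of DNA replication and of sterol synthesis rose. Of 26 measured S phase genes 25 rose and 0 fell, with a median of 1.04 (camera, adjusted p = 7.85e-20, and adjusted p = 0.0357 with an estimated correlation). The ribonucleotide reductase gene RRM2 rose by 2.19, the thymidylate synthase gene TYMS by 1.82, GINS2 by 1.71 and MCM10 by 1.61, while CDC6 was at -0.07. Of 31 mitosis genes 23 rose and 0 fell, or 24 and 0 adjusted over the list alone, with a median of 0.45 (adjusted p = 1.24e-11, and adjusted p = 0.0953 with an estimated correlation). CCNA2 rose by 1.43, BIRC5 by 1.24, TOP2A by 0.91 and KIF20A by 0.85, and MKI67, a marker of cycling cells, rose by 0.78. Of 17 cholesterol synthesis genes 13 rose and 0 fell, with a median of 1.00 (adjusted p = 1.25e-11, and adjusted p = 0.0357 with an estimated correlation). ACAT2 rose by 1.77, INSIG1 by 1.36, MVD by 1.31 and SQLE by 1.29, while their transcription factor gene SREBF2 was at 0.06 and did not pass. Counts adjusted over the list alone were the same for S phase and cholesterol synthesis.

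**Figure D2:**
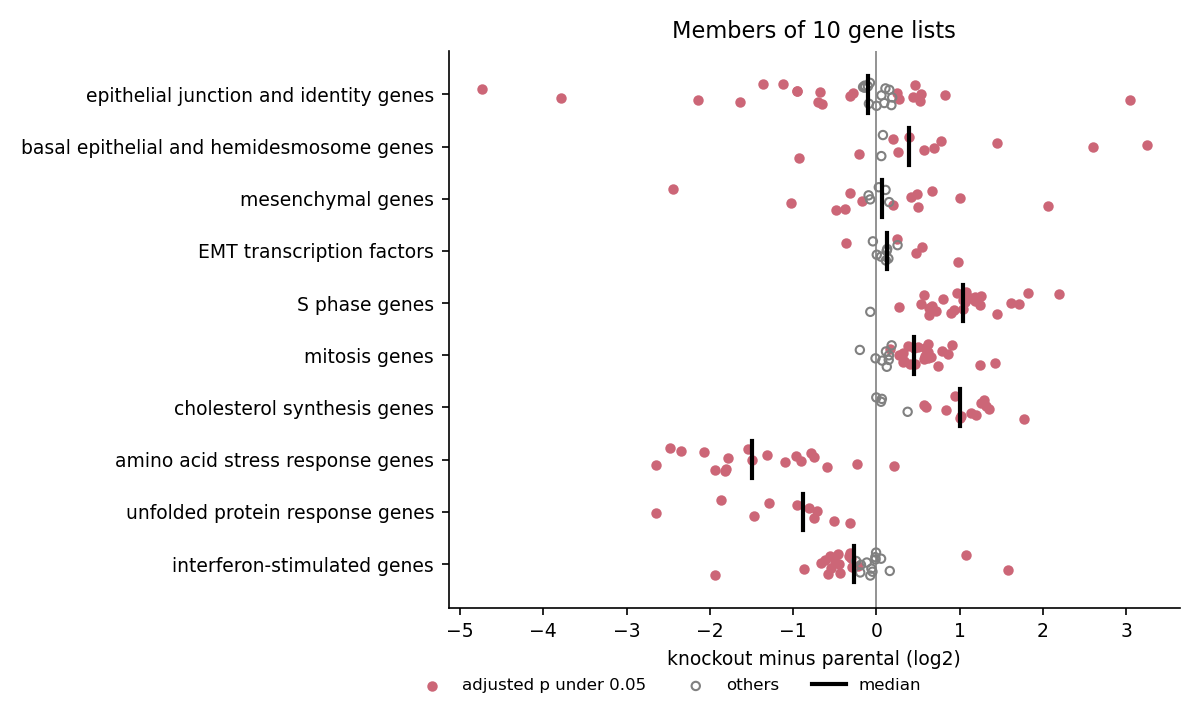
Knockout minus parental difference (log2) of each measured member of 10 gene lists, with filled points for members at an adjusted p under 0.05, open points for the others and black bars at the list medians. Amino acid stress and unfolded protein response genes lay below 0 with medians of -1.50 and -0.89, S phase and cholesterol synthesis genes above 0 with medians of 1.04 and 1.00, and epithelial genes on both sides.

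DNA damage genes moved in both directions. Of 22 double-strand break response genes 9 rose and 5 fell, or 10 and 6 adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0580, and adjusted p = 0.266 with an estimated correlation). The nuclease genes EXO1 and MRE11 rose by 1.68 and 1.44, PALB2 by 0.65 and RAD51C by 0.57, while UIMC1 (-0.36) and MDC1 (-0.19), whose product binds phosphorylated H2A.X, fell. The list passed under quantile normalisation (adjusted p = 0.0459), under centring (adjusted p = 0.0472), and without parental replicate 2, parental replicate 4 or knockout replicate 1 (adjusted p of 0.0420, 0.0340 and 0.0491). MRE11 and RAD51C lie in the stretches described below. Of 18 p53 target genes 10 rose and 3 fell, the same adjusted over the list alone, with a median of 0.24 (adjusted p = 0.0163, and adjusted p = 0.263 with an estimated correlation). PLK2 rose by 1.25 and SESN1 by 1.24, while GDF15 (-1.65) and SESN2 (-1.32) fell. Both of the latter are also known targets of ATF4.

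Interferon-stimulated genes fell as a list. Of 31 measured members 17 fell and 2 rose, or 18 and 2 adjusted over the list alone, with a median of -0.27 (camera, adjusted p = 0.00303, and adjusted p = 0.0501 with an estimated correlation). BST2 (-1.94), the RNA sensor gene IFIH1 (-0.87) and the transcription factor gene IRF1 (-0.67) fell, while IFI44L (1.57) and TRIM22 (1.07) rose. Of 14 YAP and TEAD target genes 7 rose and 3 fell, or 9 and 3 adjusted over the list alone, with a median of 0.33 (adjusted p = 0.00241, and adjusted p = 0.179 with an estimated correlation). CRIM1 rose by 1.29, FJX1 by 1.14, AMOTL1 by 0.77, AJUBA by 0.74 and CCN2 by 0.70, while the other probe sets of AMOTL1 and CCN2, not used for the list, gave 0.33 and 0.06. The 3 falls included AXL, described above with the mesenchymal genes. AMOTL1 lies in the chromosome 11 stretch that was higher, and without the stretches the median of the list was 0.21. Of 9 heat shock genes 5, among them HSPB1 (0.64), HSPA1A (0.63), HSPA1B (0.61) and HSPH1 (0.43), rose and 1, HSPD1 (-0.22), fell, the same adjusted over the list alone, with a median of 0.33 (adjusted p = 0.0163, and adjusted p = 0.0835 with an estimated correlation). HSPA1A and HSPA1B are near-identical and their probe sets may not tell them apart. Of 19 Wnt pathway genes 5 rose and 2 fell, or 6 and 2 adjusted over the list alone, with a median of 0.13 (adjusted p = 0.0390, and adjusted p = 0.0979 with an estimated correlation). The inhibitor gene DKK1 rose by 1.83 and the cyclin gene CCND1 by 1.25, while CCND2 fell by 0.96 (by its other probe set, -0.24). The Wnt call ended without parental replicate 1 or 3 or knockout replicate 2 (adjusted p of 0.0512, 0.0538 and 0.0507), without the dimmest genes (0.0619) and without the 3 stretches (0.0628).

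The other lists did not pass camera. TGF-beta response genes had 4 rises, led by the matrix glycoprotein gene THBS1 (2.38), and 4 falls, among them BAMBI (-0.93) and SKIL (-0.89), of 13 measured (adjusted p = 0.897), with a median of -0.06 and a mean of 0.05. EGFR and AP-1 pathway genes had 10 rises and 10 falls of 25, with HBEGF (-1.66), EGR1 (-1.36) and JUND (-0.81) lower and MYC (0.77) higher (adjusted p = 0.873), with a median of 0.04 and a mean of -0.13. Notch pathway genes had 7 rises, among them NOTCH1 (1.07) and MAML2 (1.31, but 0.17 by its other probe set, and in the chromosome 11 stretch that was higher), and 4 falls of 19 (adjusted p = 0.330). Hypoxia and glycolysis genes had 8 rises and 8 falls of 21, with VEGFA (-2.08) and NDRG1 (-0.92) lower and ANGPTL4 (0.99) higher (adjusted p = 0.526). Proteases and migration genes had 7 rises, among them TIMP2 (0.91) and CTSV (0.87), and 6 falls of 21 (adjusted p = 0.430). Inflammatory cytokine and NF-kB genes had 6 rises, led by CSF3 (1.80), and 6 falls, led by LCN2 (-1.73), of 25 (adjusted p = 0.526). Squamous differentiation genes had 4 rises, led by S100A8 (1.99), and 2 falls of 27 (adjusted p = 0.236). Oxidative stress response genes had 5 rises, led by TKT (0.83), and 3 falls, led by UGDH (-0.85), of 12 (adjusted p = 0.430). Myoepithelial contractile genes had 2 rises and 2 falls of 8 (adjusted p = 0.583), oxidative phosphorylation genes 3 and 2 of 13 (adjusted p = 0.567), and ribosomal protein genes 5 and 2 of 28 (adjusted p = 0.501), with RPL27 (0.67) the largest of the ribosomal rises. Adjusted over the list alone, the counts of rises and falls were 9 and 8 for hypoxia, 6 and 7 for the inflammatory list, 5 and 4 for oxidative stress, 3 and 3 for oxidative phosphorylation and 4 and 1 for ribosomal proteins, and the same as above for the remaining lists of this paragraph.

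Genes next to the H2AX locus on chromosome 11 were lower in the knockout cells. Of 19 measured neighbours 11 fell and 0 rose, the same adjusted over the list alone, with a median of -0.35 (camera, adjusted p = 0.000459, and adjusted p = 0.0523 with an estimated correlation), and -0.23 with the mean of all probe sets of a gene. HYOU1 (-2.65 and -1.25 by its 2 probe sets), a member of the unfolded protein response list, fell, the vesicle transport gene TRAPPC4 fell by 1.25, C2CD2L fell by 0.86 and the glycosylation enzyme gene DPAGT1 fell by 0.86. The neighbours were part of a longer stretch from ZPR1 to THYN1, the last measured gene above the median signal on that chromosome, in which 41 of 48 genes fell and 0 rose, with a median of -0.74. Next to it, from CEP295 to ZBTB16, 29 of 44 genes rose and 4 fell, with a median of 0.32. On chromosome 17, from MSL1 to RPL23AP87, again the last such gene, 163 of 279 genes rose and 19 fell, with a median of 0.29. Runs as long arose in 25, 58 and 0 of 1000 shuffles of the gene order. The highest running median, 0.5364 in the stretch from CEP295 to ZBTB16, also lay within the range of the shuffles (highest 0.5377). Of the genes named above, KRT14, KRT15, KRT16, JUP, ERN1, BIRC5, TOP2A, CDC6, RAD51C, TIMP2 and RPL27 lie in the chromosome 17 stretch. MRE11, MAML2 and AMOTL1 lie in the higher stretch of chromosome 11, and ST14 in the lower. The 3 stretches together held 707 genes (4.75%) and 45 of the 418 genes with at least a 2-fold difference (10.8%).

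**Figure D3:**
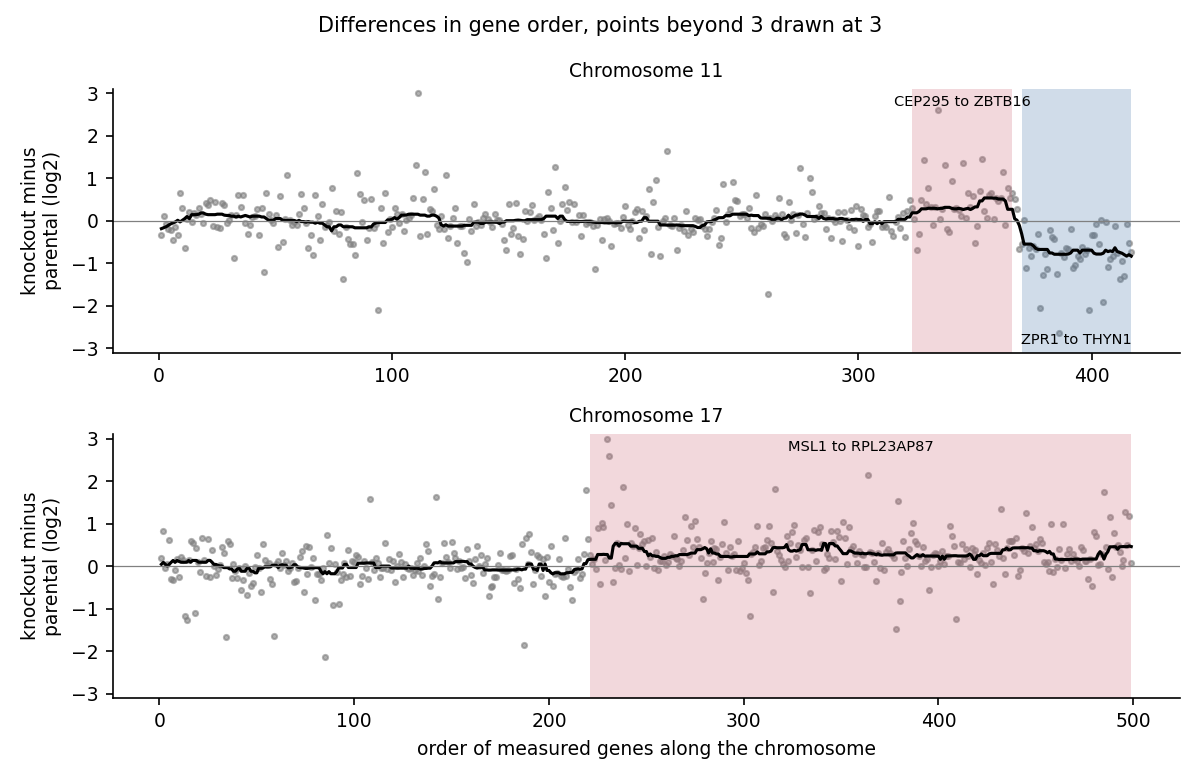
Knockout minus parental difference (log2) against the order of measured genes along chromosomes 11 and 17, with a point per gene above the median signal, a black line for the running median over 21 genes, and shading over the 3 stretches (red higher, blue lower). The line stayed below -0.15 from ZPR1 to the end of chromosome 11 and above 0.15 from MSL1 to the end of chromosome 17.

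Among the largest single differences outside these groups, the guanine deaminase gene GDA rose by 3.34, from 4.27 ± 0.24 to 7.61 ± 0.13 (n = 5 each). SESN3, the carboxypeptidase gene CPA4, SUSD2, the transcription cofactor gene VGLL3 and IGFL3 rose by 2.60, 2.59, 2.53, 2.45 and 2.36. SESN3 lies in the chromosome 11 stretch that was higher. CLGN, which encodes the chaperone calmegin, fell by 4.40, from 9.57 ± 0.09 to 5.17 ± 0.26 (n = 5 each). The lysosomal membrane protein gene LAMP3, the peptide hormone gene SPX, LURAP1L and the kinase gene STK32A fell as well (-3.65, -3.07, -2.85 and -2.79). All of these had adjusted p-values of at most 1.72e-07 and separated arrays. As for OCLN, the lower group mean of STK32A, IGFL3, BST2, DCN, CD14 and DPT lay under the median of every array, so the size of these differences is uncertain. The parental mean of GDA (4.27) and the knockout mean of LAMP3 (4.36) lay close to the array medians (4.26 to 4.35), so their sizes are uncertain too.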

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

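The tests of the fibroblast explanation, of the chromosome 17 stretch, of cell density and of random lists were chosen only after the results were seen. The others were written before their results were seen. Those among them that used the running median or the stretches still rest on a search chosen after seeing the data.

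Of 276 groups of 5 values examined for a single array far from the others, 10 had one, where chance gives about 1 in 20, or 13.8. Parental replicate 5 was low in GDA (3.85 against 4.29 to 4.43), high in SPX (9.19 against 9.10 to 9.12) and low in the mean of the amino acid stress genes (8.60 against 8.66 to 8.68). Parental replicate 3 was low in STK32A (5.98 against 6.52 to 6.71) and MRE11 (6.43 against 6.54 to 6.58), and parental replicate 1 high in MFAP5 (4.87 against at most 4.42). Knockout replicate 5 was low in RRM2 (8.11 against 8.21 to 8.23) and high in CRIM1 (10.07 against 10.01 to 10.02). Knockout replicate 1 was high in CD24 (8.61 against 8.32 to 8.39) and on the second principal component (20.2 against -9.47 to -2.52), and had the lowest array weight, 0.477.

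Among the probe sets with no gene named here the largest fall was that of 17126218, which fell by 5.66, from 10.58 to 4.92 (limma, adjusted p = 2.04e-10), and the largest rise that of 16873528, which rose by 4.24, from 3.11 to 7.35 (adjusted p = 1.15e-08). Of the 9112 probe sets that passed, 4578 had no gene named here.

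Of 100 splits of the 10 arrays into 5 and 5, drawn from 126, only 1, the real one, gave 5108 genes, and the highest of the others gave 0. Every other split mixed the groups, whose difference then entered the residual spread. A low count in those splits was therefore close to fixed in advance. The splits also cannot tell an effect of the knockout from a difference of culture, clone or batch.

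The lower genes around the H2AX locus are a pattern for which technical and biological readings differ. A fall of all genes of similar signal is argued against, since the median of the neighbours, -0.35, lay below that of all 10000 random lists matched on mean signal (2.5th percentile -0.11). HYOU1 is the only neighbour in the unfolded protein response list, so that leaving it out could hardly move the median (-0.29). Of the other 18 neighbours 10 fell and 0 rose, which argues against HYOU1 as the sole source. That list has only 10 measured genes, so it cannot show whether other neighbours follow the same response. The 21 genes centred on the locus had a median of -0.79, below the lowest window of 1000 shuffles (-0.61), and 20 of the 21 fell. These genes include members of the neighbour list, such as TRAPPC4, HYOU1, VPS11 and DPAGT1, so the window partly restates the fall already seen. A lower copy number from near the locus to the end of chromosome 11 may be part of the knockout cells' genotype. This hypothesis leaves open when it arose. DNA was not measured, and 25 of 1000 shuffles gave a run as long. A copy number shared by the whole stretch would not alone give differences this unequal. SPA17 (-2.10), MPZL3 (-2.05) and SRPRA (-1.91) fell well beyond the stretch median of -0.74. CHEK1 (-0.08), RPUSD4 (0.01) and JAM3 (-0.07) were among the 7 of its 48 genes that did not pass.

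The lower amino acid stress and unfolded protein response genes did not rest on a single array, since the median of the first list stayed at -1.48 or below with each array left out. They did not rest on the stretches, which held 0 of the 19 amino acid stress genes and 2 of the 10 unfolded protein response genes. Without those 2 the median of the second list was -0.78 and the list still passed camera. Neither check could easily fail, since 18 of the 19 and all 10 genes had fallen. Medium use and cell density at harvest cannot be told apart from an effect of the knockout, because nothing in the labels gives either and the hypoxia and glycolysis list had members moving both ways around a median of 0.0882 (0.0296 to 0.138 with an array left out). An effect of H2A.X loss stays open and untested.

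The loss of EPCAM, OCLN and ESRP1 beside higher basal keratins was set against fibroblasts in the knockout cultures. A share of other cells large enough to give the EPCAM difference of -2.14 would lower every epithelial gene about as much, yet 8 epithelial genes rose and 13 fell. The stretches hold 5 members of the list, JUP among the risen ones, so not all 8 rises bear on this. EHF (3.05), GRHL3, DSP and PPL rose outside the stretches, which argues against fibroblasts as the whole source of the loss. The fibroblast list itself passed (adjusted p = 0.0157, and adjusted p = 0.171 with an estimated correlation), with DCN, MFAP5, FBLN1, CCDC80 and PDPN (0.56 to 2.06) higher, APOD (-0.40) and DPT (-0.38) lower, and a median of 0.33, or 0.88 without the dimmest genes, so a small share of such cells may be present or the cells themselves may express these genes. Copy number of the chromosome 17 stretch is argued against as the whole source of the keratin rise, since the stretch had a median of 0.29, while KRT16, the lowest of the 3 keratins in it, rose by 1.44 ± 0.12 (SE). Whether it adds to the rise of basal genes cannot be told apart from a change of epithelial state or selection of a basal subclone, both untested, because those outside the stretches had a median of 0.25 and passed camera only without an estimated correlation.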

How the results depend on the processing

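The alternative without the 3 stretches was chosen after seeing the data, and the others before. The medians of the S phase (1.01 to 1.07), cholesterol synthesis (0.97 to 1.04), amino acid stress (-1.52 to -1.47) and unfolded protein response (-0.92 to -0.78) lists kept their direction and their call under all 20 alternatives that applied. The alternative on probe set suffixes was not run. Counts of genes were 4705 to 5128 (at least 2-fold, 406 to 422) with each array left out, and 9112 and 830 over all probe sets, which include those without a name. Against a 2-fold change as the null, treat called 175 genes. Centring the arrays gave 4905 genes, 39.2% of them higher against 44.5%. The replicate number as a block gave 4972 genes, 4740 of them shared, with 418 at least 2-fold, and changed no call of a list. Deviations of same-numbered arrays correlated at 0.199, 0.0378, 0.0489, -0.00857 and -0.0144, and 3 of 10 arrays correlated best with their own number. Both arrays numbered 1, the pair at 0.199, lay highest of their group on the second principal component (parental 5.85, knockout 20.2). Whether the numbers stand for more than a label was therefore not settled.

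The cause of the following changes was not tested. The EMT transcription factors lost their call under quantile normalisation (0.16, adjusted p = 0.0571), without the dimmest genes (0.14, 0.0657), with an estimated correlation (0.13, 0.115) and in 5 of 10 fits that left out an array (medians over all 10, 0.109 to 0.162). Wnt genes lost it without the dimmest genes (0.15, 0.0619), without the stretches (0.13, 0.0628), with an estimated correlation (0.13, 0.0979) and in 3 of 10 such fits (medians over all 10, 0.0923 to 0.152). An estimated correlation also ended the calls of the basal (0.39, 0.0835), p53 (0.24, 0.263), mitosis (0.45, 0.0953), interferon (-0.27, 0.0501), YAP (0.33, 0.179), heat shock (0.33, 0.0835), H2AX neighbour (-0.35, 0.0523) and fibroblast (0.33, 0.171) lists, which leaves 4 of 14. The epithelial list passed without the stretches (-0.14, 0.0279), and with fry (-0.10, 1.03e-05), as did the mesenchymal list (0.0688, 0.00521). Fry passed 27 of 32 lists.

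Directions turned only for results that had not passed. SNAI1 was -0.0219 under quantile normalisation, -0.0232 under centring and -0.0459 to 0.0378 with an array left out. VIM was -0.0672 to 0.135 with an array left out. For the EGFR and AP-1 list the direction of the test turned upward under quantile normalisation and without knockout replicate 1, while the median kept its sign (0.0156 and 0.0270, and 0.0132 to 0.0457 with an array left out). For the TGF-beta list it turned upward with fry, which passed (adjusted p = 0.00178), and without knockout replicate 1, while the median kept its sign (-0.0564 and -0.0443, and -0.0968 to -0.0273 with an array left out). Dim genes lie near the background of the array, where differences are compressed.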

Other observations

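The gene sets below were chosen after seeing the data, and for the synthetases the test was too. Genes of fatty acid synthesis rose beside those of cholesterol synthesis. Of 14 measured members 11 rose and 0 fell, with a median of 0.62 (camera, p = 1.53e-08, and p = 0.00424 with an estimated correlation). ACLY, which makes cytosolic acetyl-CoA, rose by 1.86 and the fatty acid synthase gene FASN by 1.75, and both lie in the stretch of chromosome 17 that was higher. Outside the stretches the desaturase gene FADS2 rose by 1.25, ACSL1 by 0.79, ACSS2 by 0.75, ELOVL6 by 0.67 and SCD by 0.64, while SREBF1, which encodes a transcription factor of this pathway, was at -0.04 and did not pass.

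Aminoacyl-tRNA synthetase genes did not all move alike. Of 13 measured genes known as targets of the amino acid response, 12 fell, with a median of -0.97, among them WARS1 (-2.48, and -1.08 by its other probe set), MARS1 (-2.24), AARS1 (-1.82) and YARS1 (-1.24), while VARS1 was at 0.08. Of the 4 other measured synthetase genes QARS1 rose by 0.58, and HARS1 (-0.05), KARS1 (-0.11) and RARS1 (0.09) did not pass.

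A shared shift of fatty acid and cholesterol synthesis was examined again without the genes of the stretches. The set was chosen after seeing the data and lost only ACLY and FASN, so this test could hardly fail. The 12 members left had a median of 0.49 (camera, unadjusted p = 3.36e-06, and unadjusted p = 0.00410 with an estimated correlation). Of these 9 rose and 0 fell. Copy number of the chromosome 17 stretch, which was not measured, may add to the rise of ACLY and FASN. It is unlikely to account for the rises outside the stretches.

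That the amino acid response, and not protein synthesis in general, lies behind the lower synthetase genes remained open. The values of 5 of the 13 genes had been seen when the set was written. For the remaining 8, the median less that of the 4 other synthetases was -0.68, a difference that 42 of 495 divisions of the genes matched (two-sided exact permutation test over genes, p = 0.0848). With all 13 the exact permutation p was 0.0277, but that set includes the genes from which the pattern may have been noticed, and genes are not independent replicates.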
